A study of Mus musculus with 18 samples.

How the data were processed

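Gene expression was measured by RNA sequencing of flow-sorted mouse retinal cells. Per the labels' protocols, RNA was extracted with the RNeasy Plus Micro kit, cDNA was made from small RNA amounts with a SMARTer Ultra Low kit, and libraries were sequenced as paired reads on a NovaSeq X Plus. Such amplification multiplies few starting molecules, so a count does not stand for an independent molecule.

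The authors deposited a table of raw counts per gene for all 18 libraries, in whole numbers, with no normalization visible in the values. DRAGEN, STAR 2.7.9a, Subread and featureCounts are named, with the build GRCm38, in the submitters' processing notes, without a role or order. Nothing in the sources used here says whether counting used strand, so reads of overlapping antisense genes could not be told apart. The same holds for reads shared between near-identical copies, such as ribosomal protein genes and their pseudogenes. The authors also deposited a table for each knockout comparison, with log2 fold changes and log2 mean CPM, a likelihood ratio score per gene, and p-values with their adjusted form, per the file headers. The submitters' processing notes name edgeR and limma without a role. The authors' deposited tables hold 12841 genes in microglia and 13330 in retina, with 76 (57 higher, 19 lower) and 744 (565 higher, 179 lower) at an adjusted p under 0.05. Of the genes called here, 15 of 17 and 235 of 255 were also past that threshold in the authors' deposited tables, and the log2 changes had Spearman correlations of 0.9999 and 1 across genes with those of the authors' deposited tables. In the authors' deposited tables Arntl has log2 changes of -0.46 in microglia and -0.36 in retina. Some microglia genes given below as not passing were past the threshold there, among them Cry2, Nr1d2, Rrm2, Top2a, Plk1, Axl and Cst7. Others, such as Mcm6 and Ctsz, were not.

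The count table had 55774 lines, of which 287 repeated an Ensembl identifier with identical counts, and 55487 genes were kept. Of these, 55141 were found in GENCODE M21, which gave gene positions on GRCm38, transcript lengths and GC content, and 4796 names written without punctuation in the table were restored from it. No line lacked a gene name and 0 sample columns were unused.

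Libraries were grouped by fraction and genotype as the labels give them. Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filterByExpr by group and TMM scaling, and called at a Benjamini-Hochberg adjusted p under 0.05. Each knockout comparison used the 9 libraries of its fraction, the interaction all 18, and the comparison of fractions the 8 control libraries. Standard errors are the log2 change divided by the root of the F statistic. CPM are scaled by the TMM factors of the fit they are quoted from, so that values of a gene can differ slightly between comparisons. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for the lists with at least 3 measured members of 38 that were written down, with alternatives that estimated the correlation for each list or used fry. Results of the microglia and retina lists past the threshold are given in the report. Count ratios of genes with 1 to 3 reads in a group carry 95% counting intervals, and a group with 0 reads was set to a floor of 3 counts over the group.

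The groupings, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Arntl, the clock genes, and for each knockout comparison the 10 higher and the 10 lower genes with the smallest p among those past the threshold with a mean of at least 1 CPM in a group and no predicted gene model name. It added from each list described up to 4 members with the smallest p and any member past the threshold, the 10 smallest p of the interaction, and for the fractions genes of each cell type list. Stmn1 and Mmp12 in microglia, Esr1 in retina and, in the closing section, Xist, F13a1, Mrc1 and the microglial genes given for the retina fraction were named after their values were seen. Some genes that the rule takes are not reported here.

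Alternatives were the size factors of DESeq2, no filter on low counts, a filter of 1 CPM in 4 libraries, the replicate number as a block, DESeq2 1.42.0, limma voom without and with quality weights, the mean level of rod or homeostatic microglia genes as a covariate, a fit over all 18 libraries, and leaving out each library. Chosen after seeing the data were a filter of a mean of 30 CPM, the number of genes with a count as a covariate, the level of 4 Y-linked genes as a covariate, and removal of each library's trend on transcript length and GC content. The design text says that both fractions were isolated together, so the same replicate number was taken to mark the same animal within a genotype, which the labels do not state outright. For control replicate 1 this pairing is in doubt, since Xist had 40.9 CPM in its microglia library and 0.084 in its retina library, although both had 0 CPM over 4 Y-linked genes. Deviations from the group means of same-numbered libraries had correlations across genes of -0.019 to 0.05 between fractions, for genes with a CPM of at least 10.

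The fits were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, all drawn from genes above a minimum mean CPM. In microglia 8% of the 2-fold and 50% of the 4-fold changes were recovered, in retina 20% and 47%, in the interaction 1% and 20%, and between fractions 1% and 35%. The simulated fits made 59, 69, 23 and 38 calls in that order, against 17, 255, 85 and 6100 in the data. The share recovered depends on how many genes change, so it does not carry over to fits with other numbers of calls. This holds most for the comparison of fractions. Genes that did not pass may still differ by such folds.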

Results

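Cells of the mouse retina were separated by flow sorting into a CD11b-positive fraction, which holds the microglia, and a CD11b-negative fraction, which holds the other retinal cells and is called retina here. CD11b is a surface protein of microglia and other myeloid cells, and dead cells were excluded with the dye DAPI. The mice either carried floxed copies of the circadian clock gene Bmal1 (controls) or lacked Bmal1 in microglia (knockouts). The comparison asks how the transcripts of microglia, and those of the cells around them, differ when microglia lack Bmal1. Each fraction had 4 control and 5 knockout libraries, 18 in all. Total counts ran from 32277156 to 47563119 per library, so that 3 counts corresponded to between 0.0631 and 0.0929 CPM, the count scaled to library size.

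The number of genes with a count differed between genotypes, in opposite directions in the 2 fractions. Microglia libraries had counts for 19029 ± 323 genes in controls and 17892 ± 488 in knockouts (mean ± SD, n = 4 and 5). Retina libraries had counts for 17640 ± 1006 genes in controls and 19235 ± 341 in knockouts, and in neither fraction did the genotypes overlap. The 10 most abundant genes took 23.7 ± 2.68% of the counts in control retina and 20.01 ± 1.33% in knockout retina, against 11.2 ± 0.225% and 10.8 ± 0.586% in microglia. Spearman correlations between libraries of the same group ranged from 0.8145 to 0.8731 across genes, and 0 pairs of libraries were identical. The labels number the samples of a group but do not state that each came from a separate mouse, so p-values measure the spread between these samples.

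**Figure D1:**
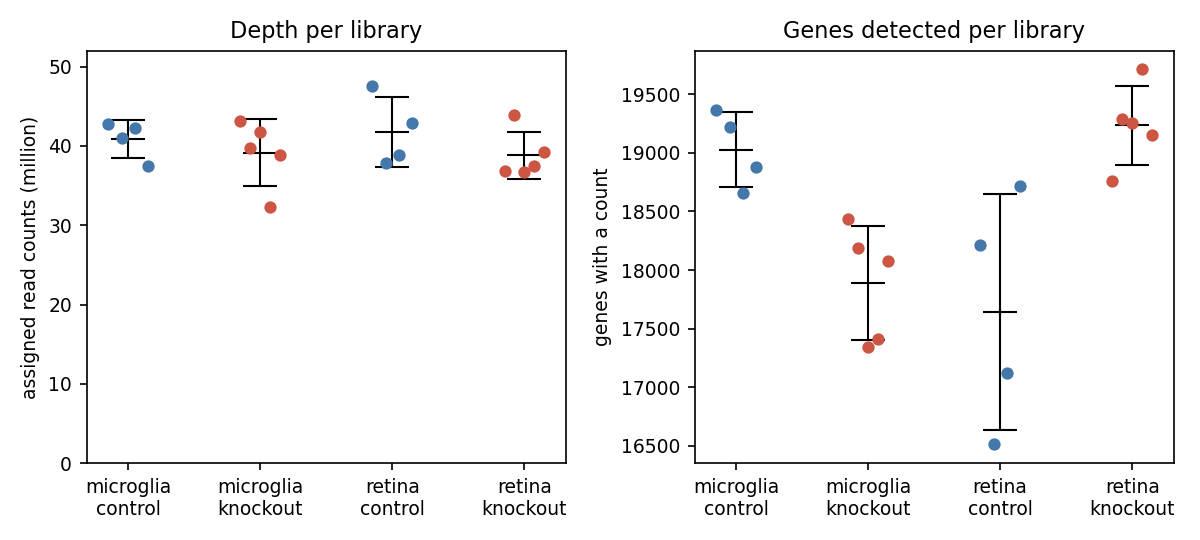
Total counts (left, scaled as marked on the axis) and genes with a count (right) for each library. Points are libraries and bars the mean and SD of each group; knockout retina libraries (18761 to 19713 genes) lie above all control retina libraries (16510 to 18715), and knockout microglia libraries (17343 to 18438) below all control microglia libraries (18654 to 19363).

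The targeted gene, listed as Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126, plus strand, GRCm38), encodes the clock transcription factor BMAL1. In microglia it had 20.7, 14.5, 9.36 and 25.5 CPM in control replicates 1 to 4 and 8.00, 1.97, 18.7, 23.1 and 12.8 CPM in knockout replicates 1 to 5. The means were 17.5 ± 7.07 and 12.9 ± 8.37 CPM, with a log2 change of -0.44 (SE 0.62, edgeR adjusted p = 0.999). In retina it had 122, 146, 129 and 102 CPM in controls and 100.4, 84.1, 83.5, 88.1 and 132 CPM in knockouts (log2 change -0.35, SE 0.17, adjusted p = 0.392). The retina value changed sign, to 0.29, with the rod gene level as a covariate. The count covers the whole gene and the labels do not say which part was deleted, so this level settles the deletion in no library, and the genotypes were taken as labelled.

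In knockout microglia the most stable differences were in Esr1, Cdkn1a, Phlda3 and Cx3cr1. Esr1, the estrogen receptor alpha gene (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614, plus strand), rose from 13.4 ± 3.20 to 519 ± 92.3 CPM (log2 change 5.28, SE 0.23, edgeR adjusted p = 2.19e-05). Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727, plus strand), which encodes the p53-induced cell cycle inhibitor p21, rose from 20.2 ± 4.64 to 239.8 ± 45.5 CPM (log2 change 3.57, SE 0.21, adjusted p = 0.000118). Phlda3, another target of p53 and a repressor of AKT signalling, rose from 1.72 ± 0.340 to 37.0 ± 6.80 CPM (log2 change 4.43, SE 0.29, adjusted p = 0.000226). Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879, minus strand), the microglial receptor for the neuronal chemokine fractalkine, fell from 5948 ± 192 to 2973 ± 215 CPM (fold 0.4998, 95% interval 0.453 to 0.551, adjusted p = 0.000118). These 4 genes passed the threshold in all 9 fits that left out a library, and the other 11 named calls did not, with a largest adjusted p from 0.078 (Fxyd5) to 0.165 (Mmp12).

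Genes of cell division, iron storage and complement were among the other microglial calls. Racgap1, needed for cytokinesis, rose from 4.44 to 27.6 CPM (log2 change 2.64, SE 0.31, adjusted p = 0.0181), and the microtubule regulator Stmn1 from 14.5 to 53.3 CPM (1.88, SE 0.25, adjusted p = 0.0304). Ftl1, the ferritin light chain, rose from 807 to 1256 CPM, Fxyd5, a regulator of the sodium pump, from 51.7 to 105 CPM, and the actin-severing factor Cfl1 by 0.45 on the log2 scale. C1qc, a subunit of the complement starter C1q, rose from 6531 ± 306 to 8853 ± 521 CPM (log2 change 0.44, SE 0.05, adjusted p = 0.0181). H2-DMa, which loads peptides onto MHC class II, rose from 329.9 to 506 CPM (0.62, SE 0.08, adjusted p = 0.0306).

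The remaining named calls had hardly any reads in either the controls or the knockouts. The mitotic kinase gene Pbk had 1 read over the control libraries and 2402 over the knockouts, a ratio per total count of 2007 with a counting interval of 359.8 to 79286. Sorbs3, a cell adhesion adaptor, had 2 and 2790 reads (ratio 1165, 322 to 9627), and Mmp12, the macrophage elastase, 1 and 1028 reads (859, 154 to 33951). Vipr2, a receptor for the peptide VIP, went the other way, with 1418 reads in controls and 2 in knockouts (849, 235 to 7015). Vipr2 passed in 0 of the 9 fits that left out a library. Such intervals, and the floors given elsewhere, cover counting error only, since amplified reads are not independent molecules.

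In total, edgeR called 17 of 14835 genes in microglia, 15 higher and 2 lower, with 855 at an unadjusted p under 0.05. DESeq2 called 237 genes, all 17 among them, limma voom 26 and the same with quality weights 46. Leaving out control replicate 1, 2, 3 or 4 left 5, 5, 4 and 5 calls. With the number of genes with a count as a covariate 5 genes passed, 4 of them among the 17.

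**Figure D2:**
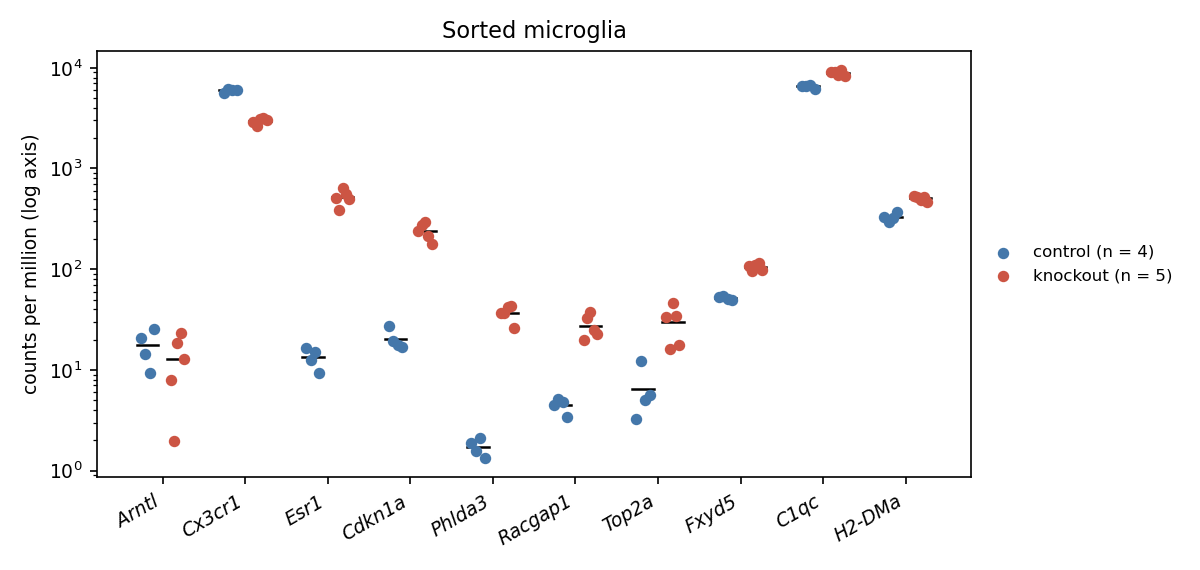
CPM of 10 genes in each microglia library, on a logarithmic axis, for controls (n = 4) and knockouts (n = 5). Points are libraries and black lines group means; Esr1 lies between 386.8 and 640.3 CPM in knockouts and between 9.31 and 16.6 CPM in controls, while Top2a (adjusted p = 0.236) and Arntl (0.999) did not pass the test.

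Cell cycle genes had the smallest p of the lists tested in microglia. All 29 measured members had positive log2 changes (median 1.55), and the list rose against other genes (camera adjusted p = 1.2e-17, and adjusted p = 0.0017 with an estimated correlation). With edgeR 0 of the 29 passed across all genes and 7 adjusted over the list alone; 10 had an unadjusted p under 0.05, DESeq2 called 6 and both limma voom fits 0. Top2a, the topoisomerase of dividing cells, had 6.49 and 29.7 CPM (2.19, SE 0.49), Mcm6 of the replicative helicase a log2 change of 1.25, and Rrm2, a subunit of ribonucleotide reductase, 6.36. The mitotic kinase gene Plk1 had 9 reads in controls and 2082 in knockouts. Markers of monocytes, border macrophages and granulocytes had a median log2 change of 0.94 in the same libraries (18 measured, 0 called by edgeR, DESeq2 or limma voom, 0 at an unadjusted p under 0.05, 0 adjusted over the list alone). That list passed with the preset correlation (adjusted p = 0.0417) and had an adjusted p = 0.741 with an estimated correlation.

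Genes of the disease-associated microglial state, induced around plaques and degenerating cells, rose as a list (28 of 30 positive, median 0.32, camera adjusted p = 6.22e-15, and adjusted p = 0.0282 with an estimated correlation). None of its 30 members passed edgeR's test across all genes and 8 did adjusted over the list alone, with 13 at an unadjusted p under 0.05, 8 called by DESeq2 and 0 by limma voom. Among them the phagocytic receptor kinase Axl had a log2 change of 0.74 (adjusted p = 0.108), the cystatin Cst7 1.55 (0.12), the cathepsin Ctsz 0.28 (0.277) and the oxidase subunit Cybb 0.82 (0.286). Antigen presentation rose as well (18 of 21 positive, median 0.34, adjusted p = 8.56e-09, and adjusted p = 0.0403 with an estimated correlation). H2-DMa passed across all genes and 2 members did adjusted over the list alone, while H2-Ab1, an MHC class II chain, stood at 0.76 (adjusted p = 0.625). The monocyte and border macrophage markers given above, from cells that also express class II genes, had a median of 0.94 in the same libraries.

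A further 8 lists, the monocyte list among them, were higher with the preset but not with an estimated correlation. Of these, complement, antioxidant and unfolded protein response genes also passed with the rotation test fry (adjusted p = 0.014, 0.0228 and 0.00174), and the other 5 did not. Across all alternatives these 3 lists kept their calls in 20, 21 and 19 of 22, with a largest camera adjusted p of 0.0778, 0.0548 and 0.351. Complement (13 of 16 positive, median 0.34, 1 called, 4 adjusted over the list alone) had a camera adjusted p = 3.75e-05 and an adjusted p = 0.051 with an estimated correlation. C1qa and C1qb, the other chains of C1q, had log2 changes of 0.36 (adjusted p = 0.0714) and 0.31 (0.128). Lysosomal genes (29 of 35 positive, median 0.18, 0 called by edgeR, 11 at an unadjusted p under 0.05, 5 adjusted over the list alone, 6 called by DESeq2, 0 by limma voom) had 4.17e-06, and adjusted p = 0.278 with an estimated correlation. They include the mannosidase Man2b1 (0.26) and Grn, the progranulin gene (0.26). Antioxidant genes (median 0.18, 20 of 26 positive, 1 called and 1 adjusted over the list alone) had 0.00279, and adjusted p = 0.0548 with an estimated correlation. Unfolded protein response genes (0.17, 16 of 22 positive, 0 called, 2 adjusted over the list alone) had 0.00412, and also adjusted p = 0.0548 with an estimated correlation. Glycolysis (0.18, 24 measured, 0 called, 2 adjusted over the list alone), phagocytosis receptors (0.13, 23 measured, 0 called, 1 adjusted over the list alone) and ribosomal proteins (0.10, 43 measured, 0 called, 0 adjusted over the list alone) had 0.00782, 0.0374 and 0.0117. They had an adjusted p = 0.58, an adjusted p = 0.278 and an adjusted p = 0.785 with an estimated correlation, and the ribosomal median turned to -0.01 with trends on transcript length and GC content removed. At an unadjusted p under 0.05 the unfolded protein response, glycolysis, phagocytosis and ribosomal lists had 5, 5, 3 and 8 genes, of which DESeq2 called 2, 2, 1 and 1 and limma voom 0.

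Some of these lists depended on single libraries. The glycolysis list had an adjusted p of 0.0889 without control replicate 1 and 0.146 without knockout replicate 2. Ribosomal proteins had 0.0875, 0.111 and 0.877 without control replicate 2, control replicate 3 and knockout replicate 5. Phagocytosis receptors had 0.111, 0.155, 0.152 and 0.139 without control replicates 3 and 4 and knockout replicates 3 and 4. The monocyte list had 0.309, 0.607, 0.359, 0.209 and 0.0502 without control replicates 3 and 4 and knockout replicates 1, 3 and 5.

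Homeostatic microglial genes, which mark resting microglia, were not called as a list (25 measured, 1 called, 4 higher and 2 lower adjusted over the list alone, median -0.09, camera adjusted p = 0.36). They were called lower among genes with a mean CPM of at least 30 (adjusted p = 0.0362) and with the number of genes with a count as a covariate (0.013). Beside Cx3cr1, the colony-stimulating factor receptor gene Csf1r had a log2 change of -0.29 (adjusted p = 0.236) and Olfml3 of 0.51 (adjusted p = 0.0541). Rod genes, present in the sorted microglia at a low level, had a median of -0.12 (27 measured, adjusted p = 0.0572), with 0 called by edgeR, DESeq2 or limma voom and 2 at an unadjusted p under 0.05. The rod list was called lower without control replicate 1 or 2 (0.00681 and 0.00518) or knockout replicate 1 or 2 (0.00111 and 0.0026), without a filter (0.0468), at 1 CPM in 4 libraries (0.0408) or a mean of 30 CPM (0.0499), with the homeostatic (0.0076) or Y-linked (0.0485) covariate and in a fit of all 18 libraries (0.0209). It was called higher with the rod level (0.0238), which is the mean of the same genes, or the number of genes with a count (0.0435) as a covariate. Clock genes driven by BMAL1 through E-box elements were not called in microglia (11 of 15 negative, median -0.28, camera adjusted p = 0.366). With edgeR 0 of the 15 passed, with 2 at an unadjusted p under 0.05, 1 adjusted over the list alone, 1 called by DESeq2 and 0 by limma voom. Cry2, a clock repressor, had 27.6 and 72.3 CPM (log2 change 1.39, SE 0.24, adjusted p = 0.0872), and Nr1d2, which encodes REV-ERB beta, 58.6 and 7.61 CPM (-2.94, SE 1.02, adjusted p = 0.662). Per3 (-0.86), Nr1d1 (-0.54) and Dbp (-0.56) did not pass either, and Nr1d1 changed sign, to 0.11, with the number of genes with a count as a covariate. In the authors' deposited table, with its likelihood ratio score, Cry2 (adjusted p = 0.00111) and Nr1d2 (0.0477) were past the threshold. Per3, Nr1d1 and Dbp were not. The Cry2 effect was not called different from that in retina (interaction log2 difference 0.31, edgeR adjusted p = 0.756).

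**Figure D3:**
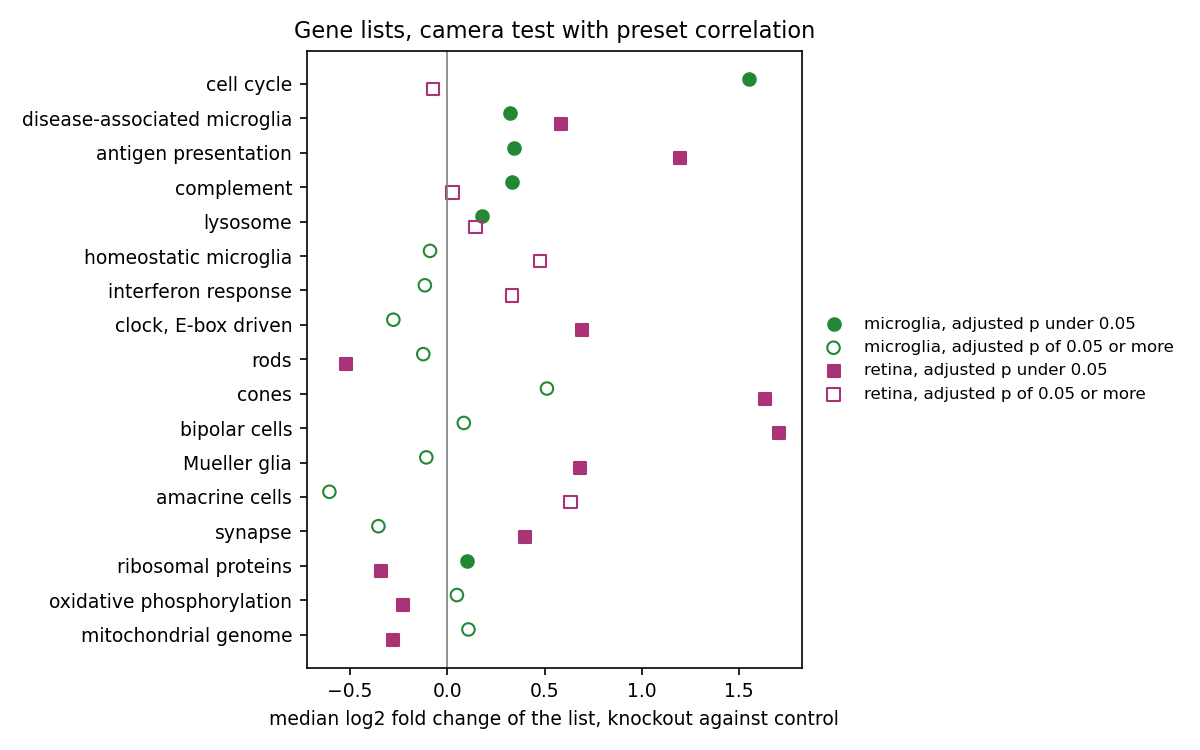
Median log2 fold change, knockout against control, of the measured members of 17 gene lists in microglia (circles) and retina (squares). Filled symbols have a camera adjusted p under 0.05 with the preset correlation; with length and GC trends removed the ribosomal median in microglia turns to -0.01 and the mitochondrial genome median in retina to 0.25, and with the rod gene level as a covariate Mueller glia and disease-associated genes in retina turn to -0.49 and -0.14; the mitochondrial and Mueller lists pass in these reversed directions.

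In the retina fraction, genes of bipolar cells and cones were higher in knockouts and genes of rods lower. These list calls held with the preset but not with an estimated correlation. With fry they passed (adjusted p = 0.00271 for bipolar cells, 0.0133 for cones and 0.0133 for rods). Cabp5, a calcium-binding protein of bipolar cells (ENSMUSG00000005649, chromosome 7, 13398132 to 13408887, plus strand), rose from 52.5 ± 8.66 to 171 ± 24.2 CPM (log2 change 1.71, SE 0.16, edgeR adjusted p = 0.00569). Of 19 bipolar genes 9 rose, 16 did adjusted over the list alone, and the median was 1.71. Car8, a carbonic anhydrase relative, rose from 16.3 to 74.6 CPM (adjusted p = 0.0189), Trpm1, the channel behind the light response of ON bipolar cells, from 136 to 749.9 CPM (2.46, SE 0.45, adjusted p = 0.0325), and the transcription factor genes Isl1 and Vsx1 by 2.09 and 1.72. Of 16 cone genes 4 rose, 13 adjusted over the list alone (median 1.63). They were the cone transducin genes Gnb3 (278 to 915 CPM, adjusted p = 0.0135) and Gnat2, the phosphodiesterase gene Pde6c, and Opn1sw, the short-wavelength opsin (663 to 2235 CPM, adjusted p = 0.0225).

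All 27 measured rod genes had negative log2 changes (median -0.52), 6 fell and 24 did adjusted over the list alone. The rod channel gene Cnga1 fell from 736 to 414 CPM (-0.83, SE 0.14, adjusted p = 0.0272), recoverin, Rcvrn, from 4022 ± 464 to 2673 ± 307 CPM (-0.59, SE 0.11, adjusted p = 0.0337), and phosducin, Pdc, from 5223 to 2854 CPM (adjusted p = 0.0373). Pde6g, Gngt1 and the arrestin gene Sag had log2 changes of -0.68, -1.08 and -0.59 and also passed. The camera adjusted p was 4.43e-24 for bipolar cells, 1.57e-22 for rods and 9.11e-13 for cones. It was lost for each with an estimated correlation, at an adjusted p = 0.0913 for bipolar cells and an adjusted p = 0.152 for rods and for cones. With the rod gene level as a covariate the medians were 0.63 for bipolar cells (adjusted p = 0.000664), 0.09 for cones (0.71) and 0.02 for the rods themselves (0.989).

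**Figure D4:**
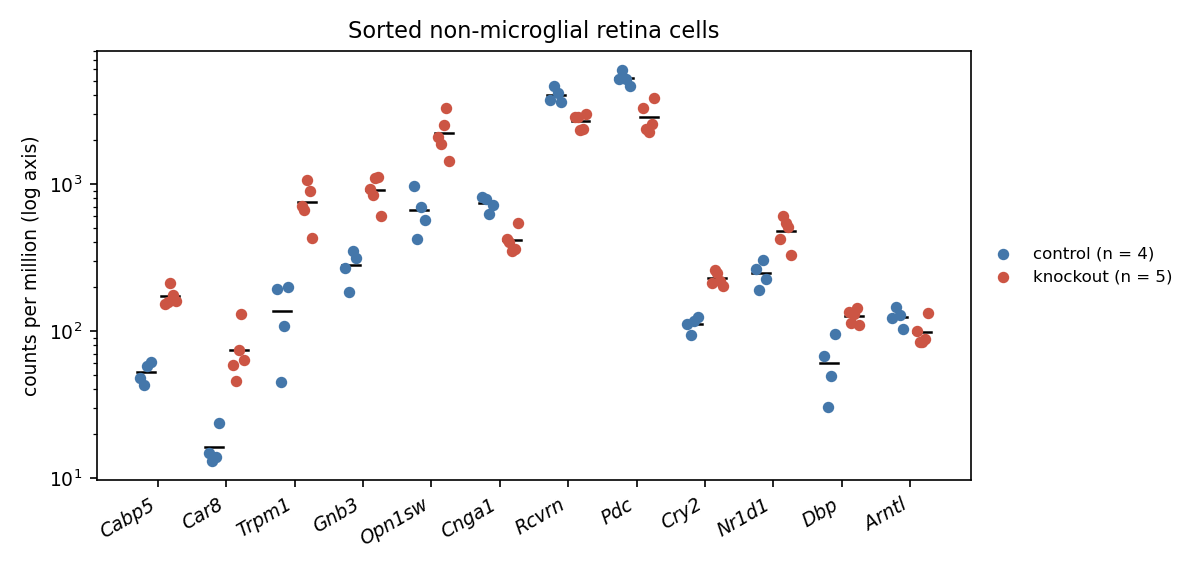
CPM of 12 genes in each retina library, on a logarithmic axis, for controls (n = 4) and knockouts (n = 5). Points are libraries and black lines group means; bipolar and cone genes such as Cabp5 and Gnb3 are higher in knockouts, rod genes such as Cnga1 lower, and Dbp (adjusted p = 0.108) and Arntl (0.392, with its sign reversed under the rod covariate) did not pass.

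Clock genes driven through E-boxes rose in knockout retina, the only retina list that passed with the preset and with an estimated correlation (12 of 15 positive, median 0.69, camera adjusted p = 7.66e-06, and adjusted p = 0.0482 with an estimated correlation). Of these, 3 rose across all genes and 5 adjusted over the list alone. Cry2 (chromosome 2, 92403646 to 92434043, minus strand) rose from 111 ± 12.5 to 228 ± 24.8 CPM (log2 change 1.04, SE 0.12, adjusted p = 0.0134), Nr1d1, which encodes REV-ERB alpha, from 246 to 480.1 CPM (0.96, SE 0.20, adjusted p = 0.0483), and Bhlhe40 by 1.53 (adjusted p = 0.0472). The median of the list was 0.25 with the rod covariate (adjusted p = 0.0146) and 0.21 with length and GC trends removed (0.0316). Cry2 passed in all 9 fits that left out a library, Nr1d1 in 1 and Bhlhe40 in 0. Tef (0.50, adjusted p = 0.0617), Dbp (1.06, 0.108) and Per3 (1.28, 0.247) did not pass. In the same libraries the number of genes with a count was higher in knockouts and rod genes were lower, as given above.

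Synaptic genes were higher (25 measured, 2 called, 6 higher and 1 lower adjusted over the list alone, median 0.40, camera adjusted p = 0.00106, and adjusted p = 0.0977 with an estimated correlation). The list passed with fry (adjusted p = 0.00264). With length and GC trends removed the median was 0.17 and the call was lost (adjusted p = 0.0513). Cplx3, the complexin of ribbon synapses, rose by 1.58 and the vesicle protein gene Syn1 by 1.54 on the log2 scale. The genes with the smallest p among higher calls also included the phosphatase receptor Ptprf (1.65), muscle-type glycogen phosphorylase, Pygm (1.59), the GABA receptor subunit gene Gabrr1 (2.45), Igsf21 (1.84) and the potassium-chloride transporter gene Slc12a5 (1.27). Lower calls included the ribosomal protein gene Rpl21 (-0.76, adjusted p = 0.0171), the collagen gene Col4a3 (-1.48), Pdia5 (-0.84), Gpsm2 (-0.83), Slc16a6 (-0.78), the photoreceptor disc gene Prcd (-0.64) and Gpx4, which reduces lipid peroxides (-0.47).

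Genes of energy supply and translation were lower as lists. With fry oxidative phosphorylation (adjusted p = 0.00213) and ribosomal proteins (0.014) passed, and the mitochondrial genome (0.109) did not. Oxidative phosphorylation (40 measured, 2 lower, 6 adjusted over the list alone, median -0.23) had a camera adjusted p = 3.33e-07 and an adjusted p = 0.0735 with an estimated correlation, and with length and GC trends removed its median was -0.08 and the call was lost (adjusted p = 0.0803). Its called members were Cox6c (-0.72) and Ndufa4 (-0.73). Ribosomal proteins (42 of 43 negative, median -0.34, 0 called by edgeR, 13 at an unadjusted p under 0.05, 0 adjusted over the list alone, 5 called by DESeq2, 1 by limma voom) had 1.03e-09, and adjusted p = 0.241 with an estimated correlation. The mitochondrial genome (12 of 13 negative, median -0.28, 0 called, 0 adjusted over the list alone) had 0.00138, and adjusted p = 0.418 with an estimated correlation, and turned to 0.25 with length and GC trends removed, where it was called higher (adjusted p = 0.0175). Its members had 2 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma voom, and without control replicate 4 the list had an adjusted p of 0.0562.

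Glial, immune and vascular lists were higher in knockout retina with the preset but not with an estimated correlation. With fry antigen presentation (adjusted p = 0.00264), disease-associated and matrix genes (0.0138 each) and glial reactivity (0.0254) passed, and Mueller glia and vessels (0.0502 each) did not. Mueller glia genes (19 of 20 positive, median 0.68, 0 called by edgeR, 9 at an unadjusted p under 0.05, 0 adjusted over the list alone, 4 called by DESeq2, 0 by limma voom) had a camera adjusted p = 7.66e-06 and an adjusted p = 0.411 with an estimated correlation. Their median turned to -0.49 with the rod gene level as a covariate, and the list was then called lower (adjusted p = 0.00203). Antigen presentation (11 of 11 positive, median 1.198, 0 called, 0 adjusted over the list alone) had 0.00886, and adjusted p = 0.117 with an estimated correlation. Disease-associated genes (0.58, 17 measured, 0 called, 2 higher and 1 lower adjusted over the list alone) had 0.012, and adjusted p = 0.355 with an estimated correlation, and turned to -0.14 with the rod covariate. Glial reactivity (0.72, 18 measured, 1 called, 2 adjusted over the list alone) and vessels (0.65, 13 measured, 1 called, 1 adjusted over the list alone) had 0.0055 and 0.0189, and each an adjusted p = 0.411 with an estimated correlation. Extracellular matrix (0.86, 17 measured, 0 called, 0 adjusted over the list alone) had 0.013, and adjusted p = 0.241 with an estimated correlation. Antigen presentation, disease-associated and matrix genes numbered 2, 5 and 4 at an unadjusted p under 0.05, with 2, 3 and 1 called by DESeq2 and 0, 1 and 0 by limma voom. With length and GC trends removed, disease-associated and matrix genes had an adjusted p of 0.187 and 0.0513, and with the rod covariate antigen presentation had 0.366.

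Leaving out control replicate 1 raised the adjusted p of the disease-associated, glial reactivity and vessel lists to 0.0713, 0.052 and 0.0713. Without control replicate 2 the disease-associated list had 0.0633, without control replicate 4 the vessel list had 0.306, and without knockout replicate 2 glial reactivity and vessels had 0.051 and 0.0917. Amacrine markers (15 measured, 1 called, 1 adjusted over the list alone, median 0.63) were not called as a list (adjusted p = 0.0855), but were called higher without control replicate 4 (0.0176), without knockout replicate 4 (0.0406), without a filter (0.0398) and at a mean CPM of at least 30 (0.00696).

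Several retina calls had next to no reads in controls. Tie1, an endothelial receptor, had 0 reads in controls and 2154 in knockouts, at least 619-fold higher against a floor of 3 counts over the group. The extracellular matrix gene Tnr had 1 and 5161 reads (ratio 4448, 798 to 175733), Psg16 1 and 1586 (1367, 245 to 54027), the Notch ligand gene Dll4 1 and 589 (508, 90.8 to 20085), Osmr 2 and 1258 (542, 149.8 to 4482) and Disp1 3 and 3116 (895, 306 to 4343). Esr1 had 9 and 734 reads, or 0.0645 ± 0.0801 and 3.66 ± 1.77 CPM (log2 change 5.79, SE 1.198, adjusted p = 0.0493). Of the called genes, 63 had no read in 2 or more control libraries. Esr1 was named here after its values were seen, as the only gene called in both fractions, where independent lists of 11 and 200 calls among 12764 shared genes would share 0.12 higher and 0.00368 lower genes.

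In total 255 of 15332 genes were called in retina, 205 higher and 50 lower (80.4% higher), with 2180 at an unadjusted p under 0.05. The share of higher calls was 63.7% of 468 calls among genes with a mean CPM of at least 30, and 37.5% of 477 with length and GC trends removed, which moved the median of all genes to -0.11. DESeq2 called 1184 genes, all 255 among them. With the rod gene level as a covariate 1 gene passed, and with the number of genes with a count 2. Leaving out control replicate 3 left 137 calls, and leaving out knockout replicate 1, 2, 3 or 4 left 141, 123, 96 and 112. Of 52 named called genes 13 passed in all 9 such fits, among them Cabp5, Gnb3, Cry2, Tnr, Tie1 and Rpl21. The others had a largest adjusted p from 0.0523 (Pdia5) to 0.133 (Sag).

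The difference between the 2 knockout effects was tested as an interaction. Most of the smallest p-values belonged to genes with reads in knockout but not control retina that were not called in microglia. Vwa5a had 199.8 and 195 CPM in microglia, 0 reads in control retina and 1397 reads, 6.65 CPM, in knockout retina, at least 401-fold higher (adjusted p = 3.52e-06). Twf2, an actin-binding twinfilin gene, had 306 and 319.6 CPM in microglia and was at least 308-fold higher in knockout retina. Rbms1 (at least 134-fold), Hps1 (357), Sec24d (339), Trim12c (122), Pusl1 (224.7) and Mcph1 (300.8) also had 0 reads in control retina, with Hps1 at 30.3 and 41.5 CPM and Mcph1 at 6.13 and 10.5 CPM in control and knockout microglia. Rassf4 had 252 and 199.9 CPM in microglia and 2.48 and 24.8 CPM in retina (log2 difference -3.65, SE 0.39, adjusted p = 0.000137). Vipr2 had 9.20 and 0.0111 CPM in microglia and 30.3 and 59.1 CPM in retina (adjusted p = 3.95e-05).

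Bipolar, clock and ribosomal lists were among those whose knockout effect differed between the fractions. The median difference, microglia effect minus retina effect, was -1.71 for bipolar cells (camera adjusted p = 1.28e-06), -1.01 for E-box clock genes, 0.39 for ribosomal proteins, 0.41 for rods and 1.10 for cell cycle genes. Of 37 lists 13 passed, 7 up and 6 down, and 0 did so with an estimated correlation, where the adjusted p ran from 0.107 for cell cycle to 0.496 for rods. For single genes edgeR called 85 of 18128, 14 with the larger value in microglia and 71 in retina. Of the 71, 23 had no read in any control retina library and 7 had 1 to 3. The 10 genes named above passed in all 18 fits that left out a library, and 6 of them passed in every other alternative. The count went to 51 without microglia control replicate 3 and to 143 without retina control replicate 4, and with the replicate number as a block, which pairs the fractions, to 9. The difference for Esr1 was -0.66 (adjusted p = 0.83).

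The sort itself was read from control microglia against control retina. Csf1r had 19519 ± 1533 CPM in microglia and 0.0268 ± 0.019 CPM, 5 reads, in retina. P2ry13, a purine receptor of microglia, had 350596 reads in microglia and 1 in retina. All 25 homeostatic microglia genes and all 19 antigen presentation genes were higher in microglia (25 and 19 adjusted over the list alone, adjusted p = 0.00126 and 0.0138 with an estimated correlation). All 27 rod genes were lower (27 adjusted over the list alone, median -4.35, camera adjusted p = 2.36e-38, and adjusted p = 0.0501 with an estimated correlation). Rod transcripts remained visible in microglia, with Rcvrn at 186 CPM against 3793 CPM in retina.

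Of the other retinal types, bipolar cells had 10 of 19 lower (12 adjusted over the list alone), cones 8 lower and 1 higher of 16 (9 and 1), and Mueller glia 7 lower and 1 higher of 20 (8 and 1). Their camera adjusted p of 0.000549, 0.00428 and 0.0208 was lost with an estimated correlation, at an adjusted p = 0.438 for bipolar cells, an adjusted p = 0.405 for cones and an adjusted p = 0.498 for Mueller glia. Otx2, a photoreceptor and bipolar transcription factor, fell by 4.07 on the log2 scale and the Mueller glia carbonic anhydrase gene Car2 by 3.22. Markers of monocytes and border macrophages were also higher in the CD11b-positive fraction, with Ms4a7 at 2741 reads against 0 (at least 935-fold) and Ccr2 at 2631 against 1 (8 of 11 called, 8 adjusted over the list alone, camera adjusted p = 0.0362, and adjusted p = 0.484 with an estimated correlation). In total 6100 of 15188 genes were called, 3458 higher in microglia and 2642 lower, and 22 of 36 lists, 12 higher and 10 lower, of which 6 held with an estimated correlation.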

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

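In this part the splits of the samples and the tests on cell cycle detection, p53 targets and length or GC bias were fixed before their results were seen, and the tests on Cx3cr1, homeostatic genes, library complexity in retina, cell cycle genes with reads in all or only some libraries, rod loss, genes without a read and monocyte markers were chosen only after the result was seen. Intervals of list medians and of their differences, here and in the last part, come from 10000 resamplings of the genes of a list. They treat the genes as independent and carry no spread between samples.

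Of 253 groups of values examined, 20 held a sample far from the others, where about 12.7 would by chance. That rate does not hold for genes with reads in a single library of a group, which are always flagged. Several flags below are of this kind, so no excess over chance can be read from the count. Ribosomal protein genes took 0.572% of the counts in retina control replicate 4, against 0.421 to 0.445% in the other controls. In microglia, single reads set Pbk apart in control replicate 2 (0.0242 CPM), Mmp12 in control replicate 3 (0.0238 CPM) and, with 2 reads each, Sorbs3 in control replicate 4 (0.0513 CPM) and Vipr2 in knockout replicate 2 (0.0518 CPM), where the other libraries of the group had 0. Plk1 had 0.205 CPM in control replicate 4 against at most 0.0227, and Sparc 7368 CPM in knockout replicate 4 against 5845 to 6234. In control retina the same held for Tnr in replicate 2 (0.0299 CPM), Psg16 in replicate 1 (0.0209), Osmr in replicate 2 (0.0599) and Dll4 in replicate 3 (0.028), with 0 elsewhere. Also in control retina, Rpl21 had 84.6 CPM in replicate 1 against 100.4 to 103, Car8 23.6 in replicate 4 against 13.02 to 14.7, Gngt1 1202 in replicate 3 against 1745 to 1759, and Hes1 6.82 in replicate 2 against 10.4 to 10.9. In knockout retina, replicate 4 stood apart in Pde6c (236 CPM against 94.0 to 124), Hes1 (26.4 against 15.995 to 18.03) and Itgb5 (172 against 85.5 to 106), and replicate 5 in Ebpl (186 against 137 to 152) and H2-K1 (18.5 against 50.6 to 59.8).

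The knockout effect differed between the fractions, by edgeR's interaction test, for 18 of the named genes. The log2 difference, microglia minus retina, was 3.63 for Racgap1 and -3.65 for Rassf4. Fitted differences of genes with few or no reads in a group are no bounds. They were -5.97 for Olfml3 and -6.47 for Nfkb2, each with 5 reads in control retina, 11.87 for Pbk, 8.97 for Sorbs3, 15.51 for Mmp12, -10.31 for Vipr2, -18.91 for Tnr and -9.54 for Disp1. For genes without a read in control retina they were -11.10 for Vwa5a, -9.43 for Rbms1, -10.63 for Twf2, -10.41 for Hps1, -10.76 for Sec24d, -9.63 for Trim12c, -10.50 for Pusl1 and -9.89 for Mcph1.

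With the preset correlation 13 lists differed between the fractions, and 0 did with an estimated correlation. The median differences above 0 were 0.39 for ribosomal proteins, 0.23 for oxidative phosphorylation, 0.44 for the mitochondrial genome, 0.41 for rods, 1.10 for cell cycle, 0.13 for glycolysis and 0.23 for the unfolded protein response. Those below 0 were -1.71 for bipolar cells, -0.85 for Mueller glia, -1.01 for E-box clock genes, -1.09 for cones, -0.84 for synapse and -0.71 for glial reactivity.

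Regrouping the same libraries made chance an unlikely source of the counts of knockout and interaction calls. For these, 100 of the 126 possible splits were run. The splits do not tell genotype from another difference between the same groups, such as the number of genes with a count. The real split is among those counted, so 1 of 100 and 1 of 35 are the smallest shares possible. The splits treat the samples as separate animals, which the labels do not state. In microglia 1 of 100 splits, the real split with 17 calls, reached that count, and the highest other gave 1. In retina it was again 1 of 100, with 255 calls against at most 1, for the interaction 1 of 100, with 85 against at most 28, and between fractions 1 of 35, with 6100 against 0. Every other split between fractions mixed microglia and retina libraries within a group, so low counts there were foreseeable and add no support.

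Esr1 rose 38.9-fold in knockout microglia while Cx3cr1 fell to a fold of 0.4998 (0.453 to 0.551). The labels do not name the driver of the deletion, and a candidate explanation is an inserted recombinase fused to an estrogen receptor domain in place of 1 of the 2 Cx3cr1 copies, which predicts a fold of 0.5 for Cx3cr1 and more Esr1 reads in every knockout library (386.8 to 640.3 CPM against 9.31 to 16.6). The other 24 homeostatic genes had a median log2 change of -0.0759 (-0.144 to 0.0711). This argues against a loss of the group as large as the fall of Cx3cr1. A smaller loss stays open, since the interval carries no spread between samples. The list with Cx3cr1 was also called lower among genes with a mean CPM of at least 30 (camera adjusted p = 0.0362) and with the genes-with-a-count covariate (0.013). As far as the labels tell, no library carries a recombinase without the floxed gene, so effects of the recombinase and of Bmal1 loss were not separated here, and a regulation of Esr1 and Cx3cr1 by BMAL1 stays open.

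Bipolar and cone genes were higher and rod genes lower in knockout retina as lists with the preset correlation, but not with an estimated correlation (adjusted p = 0.0913, 0.152 and 0.152), with 9 of 19, 4 of 16 and 6 of 27 members called by edgeR. Each list passed with fry (adjusted p = 0.00271, 0.0133 and 0.0133). The 17 of 19 bipolar genes with reads in all controls had a median log2 change of 1.706 (1.53 to 1.94), as did all 19. The rise thus does not rest on genes without a read in a control library. These 17 genes are nearly the whole list, so their median could not settle whether lower complexity of control libraries played a part. Fewer sorted rods would raise the other cell types alike. Bipolar genes and cone genes (1.631, 1.39 to 1.81) had similar medians. Those of amacrine genes (0.6325, -0.110 to 1.06, not called as a list) and Mueller genes (0.6825, 0.639 to 0.836, 0 called by edgeR, 9 at an unadjusted p under 0.05, 4 called by DESeq2 and 0 by limma voom) were lower. Bipolar genes lay 0.865 (0.557 to 1.18) above the pool of these 3 types. With the rod gene level as a covariate the medians were 0.63 for bipolar cells (camera adjusted p = 0.000664) and 0.09 for cones (0.71), and retina calls fell from 255 to 1. Since the intervals carry no spread between samples, fewer rods as the whole cause were not excluded. A length or GC bias is argued against by bipolar minus rod genes of 2.471 (1.815 to 2.69) with those trends removed, against 2.225 before. For called genes without a read in most control libraries complexity cannot be told apart from regulation, because higher calls exceeded lower calls 1.753 to 1 even among genes of at least 30 CPM, between the bounds set for either reading, while 317 genes had reads in all knockout and at most 1 control library and 30 the reverse. A different yield of bipolar and cone cells in the sort, or a change within those cells, may also underlie the pattern and was not tested.

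Cell cycle genes as a list, and the single p53 targets Cdkn1a and Phlda3, were higher in knockout microglia. Lower complexity of these libraries is argued against for the 11 cell cycle genes with reads in all 9 of them, with a median log2 change of 0.8743 (0.637 to 1.42). The median over all 29 genes of the share of knockout libraries with reads minus that of control libraries, the measure fixed before, was 0 percentage points (0 to 25) and decided nothing, since these 11 genes cannot differ in it. The other 18 genes had a median of 27.5 points (15 to 50). This is opposite to the -20 points of other genes no more abundant and without reads in some library. Of those, genes with log2 changes of 1.46 to 2.92 had 25 points (10 to 25). The share so restates the higher level of the 18 genes, which lack reads in some library. By itself it does not separate lower complexity from regulation. A p53 response is a hypothesis that passed a test that could have failed. Of 36 further targets listed without having seen their values, 30 were measured and 20 positive. Their median log2 change was 0.38, with an interval that came close to 0 (0.0105 to 0.797). The measured targets had a camera p of 0.00724 with an estimated correlation. Of these 30, 0 were called by edgeR, 6 had an unadjusted p under 0.05, all higher, 3 passed adjusted over these alone, and DESeq2 called 3 and limma voom 0. Monocytes, border macrophages or granulocytes in the CD11b gate, which does not remove them, cannot be told apart from a change within microglia, because their 18 measured markers, 0 of them on another list, had a median of 0.9391 with an interval (0.332 to 1.29) that holds the value of 1 set as the bound. The most abundant of these markers had wide spreads, F13a1 at 80.1 ± 79.3 and 131 ± 73.5 CPM and Mrc1 at 62.2 ± 70.7 and 128 ± 58.3 CPM. This source stays open for the higher disease-associated and antigen presentation lists as well.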

How the results depend on the processing

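In this part the mean of 30 CPM, the Y-linked and genes-with-a-count covariates and the length and GC trend were alternatives chosen only after seeing the data. In leave-one-out fits, 1058 of 1355 values of named genes kept their direction and side of the threshold, 289 became weaker, 8 stronger and 0 reversed. Of the 1774 under other alternatives 1328 kept both, 373 became weaker, 70 stronger and 3 reversed. Of called lists, 203 of 225 leave-one-out values and 250 of 323 others kept the call, and 5 reversed. Calls in microglia (17) went to 8 without a filter, which tests more genes, 237 with DESeq2, 26 with limma voom, 46 with quality weights, 6 with the rod covariate, 32 in a fit of all 18 libraries and 5 with the genes-with-a-count covariate, and to 4 to 21 when a library was left out, with fewer samples. In retina (255) they went to 120 without a filter, 1184 with DESeq2, 1 with the rod covariate, 134 with the homeostatic covariate, 468 at a mean of 30 CPM, 153 with the Y-linked covariate, 2 with the genes-with-a-count covariate, 477 (179 higher) with length and GC trends removed, and 96 to 342 when a library was left out. The rod and genes-with-a-count covariates themselves differ between the genotypes. Interaction calls (85) went to 1074 with DESeq2, 145 with limma voom, 128 with quality weights, and 51 to 143 when a library was left out. Calls between fractions (6100) stayed between 4436 and 7536. The 11 called lists in microglia became 3 with an estimated correlation and 6 with fry (8 to 14 leaving out a library). The 14 in retina became 1 with an estimated correlation and 8 with the rod covariate (11 to 16 leaving out a library). Mueller glia are among those 8 only in the reversed direction. Arntl ranged from -0.76 to -0.17 in microglia and from -0.49 to -0.26 in retina when a library was left out. With the rod covariate the retina values of Arntl (0.29), Dkk3 (-0.23), H2-K1 (-0.043), disease-associated genes (-0.14) and Mueller glia (-0.49) reversed, and the medians of matrix (-0.03) and glial reactivity genes (-0.17) fell below 0. The same covariate took the medians of bipolar cells to 0.63, of cones to 0.09 (adjusted p = 0.71) and of rods to 0.02 (0.989), and the reversed Mueller list passed (0.00203). The genes-with-a-count covariate reversed Mueller glia in retina (-0.0119) and Nr1d1 in microglia (0.11), and removing length and GC trends the ribosomal list in microglia (-0.0118) and the mitochondrial genome in retina (0.25, passing at 0.0175), and ended the calls of oxidative phosphorylation (-0.08) and synapse (0.17) in retina. The causes of these changes were not tested, and leaving out a library raised some counts of calls and lowered others.

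With the replicate number as a block, calls went to 2 in microglia, 0 in retina by edgeR (2208 genes at an unadjusted p under 0.05, 1184 by DESeq2 and 363 by limma voom without the block) and 9 for the interaction. Whether the number pairs the genotypes was not settled. In microglia same-numbered control and knockout libraries had correlations of deviations of -0.04 to 0.001, and no replicate correlated best with its own number. In retina they had -0.007 to 0.094, and replicates 2, 3 and 4 (0.032, 0.02 and 0.094) correlated best with their own number. The loss of the retina calls with the block therefore stays a limit. The block changed no other count by over 1.5 times. Low counts limit genes near the floor, where fitted folds are no bounds.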

Other observations

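In this part all tests were chosen only after the result was seen, apart from the gene lists and the edgeR fits, which were fixed before.

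Several single genes of groups not described so far also passed in knockout retina. Slc6a9, the glycine transporter of amacrine cells, rose from 92.0 ± 33.0 to 206 ± 27.4 CPM (log2 change 1.16, adjusted p = 0.038), the muscle-type phosphofructokinase gene Pfkm from 50.1 ± 9.90 to 123 ± 37.0 CPM (1.29, adjusted p = 0.0366) and Itgb5, an integrin of phagocytosis, from 50.1 ± 12.2 to 113 ± 33.6 CPM (1.18, adjusted p = 0.0461). Cst3, the cystatin C gene, fell from 1474 ± 151 to 1062 ± 79.4 CPM (-0.47, adjusted p = 0.0412). Nfkb2 had 5 reads in controls and 625 in knockouts (adjusted p = 0.0306), too few in controls for the fitted change to be a bound. The glutamate receptor gene Grin1 (1.80, adjusted p = 0.0607) and the growth factor gene Igf1 (2.00, 0.0606) did not pass, nor did the class I antigen genes H2-K1 (1.24, 0.124) and Tap2 (1.57, 0.172). Immediate early genes had 17 of 19 positive changes (median 0.27, camera adjusted p = 0.0831), with 0 called by edgeR, 6 at an unadjusted p under 0.05, 3 higher and 2 lower adjusted over the list alone, 5 called by DESeq2 and 1 by limma voom. The list was called higher without control replicate 4 (0.00803) or knockout replicate 3 or 4 (0.0434 and 0.0417), without a filter (0.0185), with fry (0.0485) and in a fit of all 18 libraries (0.00666).

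In knockout microglia, Gapdh of glycolysis had a log2 change of 0.57 (adjusted p = 0.108), the stress transcription factor gene Atf5 2.66 (0.163), the complement protease gene C1ra 2.45 (0.419) and the clock repressor gene Nfil3 1.79 (0.552), none past the threshold. Interferon response genes had a median of -0.12 while the test pointed up (30 measured, camera adjusted p = 0.909), with 0 called by edgeR, 1 at an unadjusted p under 0.05 and 0 by DESeq2 or limma voom. The list was called higher without control replicate 1 (0.00999) and lower with the rod gene level as a covariate (0.0344).

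Xist, transcribed from the inactive X chromosome of females, had 40.9 CPM in microglia control replicate 1, 37.4 in microglia knockout replicate 1 and 13.3 in retina knockout replicate 1. These libraries and retina control replicate 1 had 0 CPM over 4 Y-linked genes, but Xist was at 0.084 CPM in retina control replicate 1. The remaining libraries had 41.0 to 112 CPM over the Y-linked genes.

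Transcripts of microglia were rare in the retina fraction. Csf1r had 5 reads in controls and 7 in knockouts, P2ry12 348 and 0, Tmem119 262 and 3, and Cx3cr1 77 and 2, so the Esr1 reads of knockout retina (734) came with few reads of these genes.

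The higher E-box-driven clock genes in knockout retina (median 0.69, 0.210 to 1.04) could come from a different clock phase at sampling, as a hypothesis. Such a shift would lower the genes that REV-ERB represses, Arntl included, but their median was 0.3475 with an interval of -0.279 to 0.911, which leaves it open. The labels give no time of day.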
